A study of Mus musculus with 24 samples.

How the data were processed

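Serum exosome miRNA was measured on 24 arrays in 6 groups of 4, male BALB/c mice given toosendanin (TSN, a plant triterpenoid) at 80 mg/kg or vehicle for 3, 9 or 21 days. Per the labels' protocols, total RNA was extracted with kits, labelled with Cy3 and hybridised to a one-colour mouse miRNA array. The labels do not say whether a sample is a single animal or a pool, so p-values measure the spread between these samples.

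The values of the scanner files are intensity, deposited per array. Per the file headers, Feature Extraction 10.7.1.1 subtracted the background and corrected a spatial trend, and recorded no scaling between arrays. Each array held 58594 spots, of which 56430 were not controls, for 4415 probes of 1881 miRNAs, with a median of 15 spots per probe and no saturated spot. Names are those of the array's design. The authors' processed values cover 1882 entries, 1881 of them miRNAs and 1 a control, and are taken here as log2 because they rose with the log2 of the scanner values; the authors' scaling and centring are not stated and stay unknown. Their column medians lay between 4.373 and 4.4, their values correlated with the scaled scanner values across miRNAs at r of 0.937 to 0.971, and 23 of the 24 columns matched their own array best (the exception was control day 9 replicate 4).

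Control spots and spots the software marked as outliers were left out and spots of a probe were averaged. Each array was divided by its 75th percentile over the 261 probes well above background on all 24 arrays. A floor of 0.0135 (-6.21 on the log2 scale) was then set, which is the median over arrays of the lowest scaled signal well above background, and log2 was taken. Values at the floor have no order, and the brighter TSN arrays also measured signals below it. The probe with the highest mean over the 24 arrays stood for a miRNA. A probe was well above background on an array where the software gave this for more than a 0.5 share of its spots. The 444 miRNAs well above background on all 4 arrays of at least 1 group were tested, and 152 were well above background on all 24 arrays. Where no array of a group was well above background, the group has only a bound, and the difference is given as at least N-fold, from the brighter group's mean against the higher of the lowest signal well above background and the miRNA's own signal on each array of the dimmer group.

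One limma fit (limma 3.58.1, R 4.3.3, the data.table package in version 1.17.8) covered the 6 groups, with moderated standard errors (prior degrees of freedom 1.27) and Benjamini-Hochberg adjustment at 0.05 over the 444 miRNAs in each of 12 comparisons. These were TSN against control at each day, the differences of these effects between days (interaction terms), and days against each other within each arm. All limma tests were two-sided. A change is the log2 difference between group means, with its standard error (SE). Array measures were compared with an exact two-sided permutation test over the 70 allocations of 8 arrays, whose smallest p is 0.0286.

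The 4 slides and 3 scan dates were read from the headers. Slide 1 held control days 3 and 9, slide 2 control day 21 (its 4 arrays were read with a grid file), slide 3 TSN day 3 and slide 4 TSN days 9 and 21. No slide or scan date held both arms, so arm and slide cannot be told apart. Only control day 9 against day 3 and TSN day 21 against day 9 lie within a slide. The replicate number is the column on the slide. In TSN against control at day 9, arrays of the same number deviated together in 4 of 4 pairs (r across miRNAs of 0.202 to 0.353), and each array matched its own number best, where the shared number is the slide column, the only link between these arrays in the files. No such pattern was seen in the other 8 comparisons of 2 groups.

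Before the data were examined, the comparisons, 18 miRNA lists, most alternatives and the rule for the miRNAs to name were fixed. The rule took miR-106b-5p (named in the series title) everywhere, the 8 highest and 8 lowest called miRNAs whose groups did not overlap in each TSN comparison, the 2 smallest adjusted p of each list, and the 3 smallest adjusted p per direction in the other comparisons. The lists were liver-enriched, erythroid, platelet, leukocyte, muscle and heart, brain, pancreas, epithelial (gut and kidney), vascular, stellate cell and fibrosis, the miR-17 superfamily, the let-7, miR-34, miR-30 and miR-15/16 families, the Dlk1-Dio3 and Sfmbt2 clusters, and late miRBase entries (those with high miRNA numbers). Lists were tested with camera (preset correlation 0.01), and 14 of the 18 had at least 3 tested members. The brain, pancreas, epithelial and miR-34 lists did not.

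Alternatives to the scaling were the 75th percentile over all probes, quantile normalization, 4 spike-in probes, none, and the authors' values. Other alternatives were normexp background correction (offset 50), the software's total gene signal, the mean of a miRNA's probes, a halved floor, no filter, a filter on all 24 arrays or on the compared groups, an intensity trend with robust estimation, array weights, the replicate block, the compared groups alone, a 2-fold minimum, and each array left out in turn. The slide as a random block was tried in an additive model of arm and day. For lists, camera with an estimated correlation and fry were run. Scaling to the labelling spike-ins alone, scaling to the hybridisation spike-ins alone, and leaving out the 2 dimmest control arrays of each day were chosen after seeing the data.

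The fit was tested on simulated data made for the day 3 comparison, with 444 miRNAs and 50 changed at each size. It recovered 90% of those changed by a log2 size of 1 and 98% at a size of 2, with 5 false calls among 344 unchanged miRNAs and 0 calls where nothing changed. The simulated arrays were built from control day 3 means with independent noise, and their brightness cancelled in the scaling. They held no additive background, difference in detection or slide effect, so errors from these were not tested. On these arrays, precision is limited by their number and by the signal over background given in the results. Neighbouring genes were taken from a reference of another build than the array's, so no coordinates are given.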

Results

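MicroRNA in serum exosomes was measured on 24 arrays from male BALB/c mice given toosendanin (TSN), a triterpenoid of Melia plants that injures the liver at high doses, at 80 mg/kg, or vehicle. Serum was taken after 3, 9 or 21 days of dosing, with 4 arrays per group in 6 groups, so n = 4 per group applies to every value below. The series title places the data in a study of miR-106b-5p, vimentin and the adaptive response of the liver to drug injury. The control arrays had 184 to 351 miRNAs well above background and the TSN arrays 379 to 471, of 1881 on the array. The means were 434, 440 and 460 in the TSN groups of days 3, 9 and 21 against 236, 221 and 273 in the controls (exact two-sided permutation p = 0.0286 at each day, the smallest possible; adjusted p = 0.0429 over 9 tests). Before scaling, the 75th percentile of the signal was 7.23, 11.8 and 5.87 times higher in the TSN groups at the same days (exact p = 0.0286 and adjusted p = 0.0429 at each day), and the labelling spike-ins were 3.37, 3.52 and 3.32 times higher (exact p = 0.0286, adjusted p = 0.033, a measure added after the data were seen). All changes below are log2 differences relative to each array's 75th percentile, and a rise or fall is relative to it. No slide held both arms, so a difference between arms and a difference between slides cannot be told apart.

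**Figure D1:**
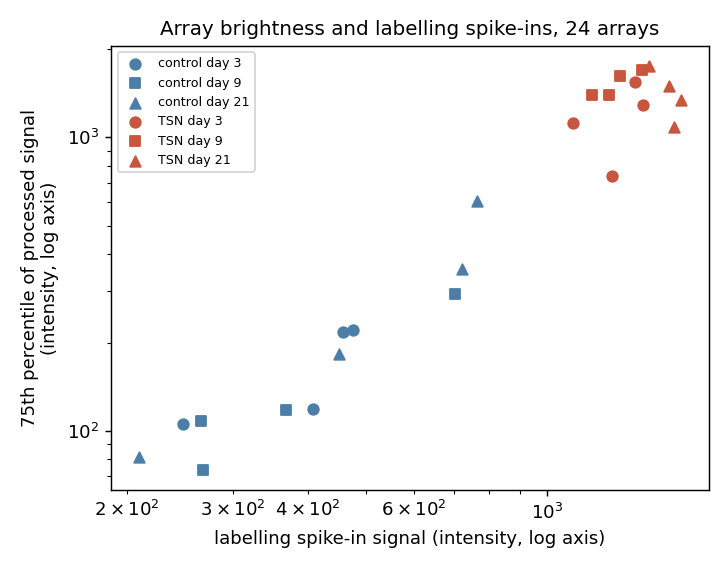
The 75th percentile of processed signal (intensity units, log axis) is plotted against the labelling spike-in signal (intensity units, log axis) for each of the 24 arrays, coloured by arm. The 12 TSN arrays lie between 736.8 and 1748 on the vertical axis and the 12 control arrays between 73.55 and 609.2.

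In every TSN group, miR-106b-5p rose against the control group of the same day. The change was 1.37 at day 3 (SE 0.189, limma adjusted p = 5.23e-06), 2.37 at day 9 (SE 0.189, adjusted p = 5.48e-09) and 1.05 at day 21 (SE 0.189, adjusted p = 0.000144). Group means were 0.27 (SD 0.288), 1.39 (SD 0.205) and 0.30 (SD 0.223) in the TSN groups and -1.10 (SD 0.28), -0.98 (SD 0.374) and -0.75 (SD 0.232) in the controls, with the signal well above background on all 24 arrays. The rise stayed positive and past the threshold at all 3 days under each of the 9 alternatives of scaling, background and authors' values. In the reference annotation (GRCm38.p6), Mir106b, Mir93 and Mir25 lie within the span of Mcm7. Its cluster neighbours miR-93-5p and miR-25-3p rose at day 9, by 1.08 (adjusted p = 4.31e-05) and 1.41 (adjusted p = 1.68e-05), and passed at neither day 3 (-0.06 and 0.05) nor day 21 (-0.19 and -0.36); both were chosen after their values were seen.

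**Figure D2:**
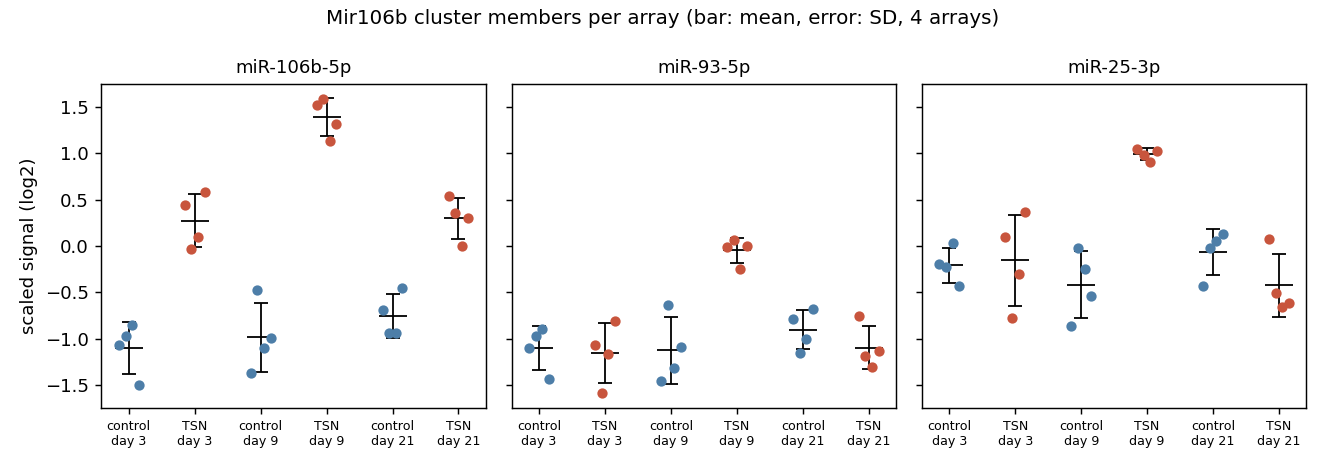
Scaled log2 signal of miR-106b-5p, miR-93-5p and miR-25-3p on each of the 4 arrays of the 6 groups, with the mean (bar) and SD (error line). The miR-106b-5p means of the TSN groups are 0.27, 1.39 and 0.30 and those of the controls -1.10, -0.98 and -0.75 at days 3, 9 and 21, and the rise of miR-106b-5p flipped under none of the 9 alternatives of scaling, background and authors' values.

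TSN against control at day 3 asked what 3 days of dosing changed. Among miRNAs measured on every array of both groups, miR-6354 rose by 2.39 (SE 0.216, adjusted p = 4.99e-08), miR-5100 by 2.06 (SE 0.186, adjusted p = 4.99e-08), miR-26a-5p by 1.79 (SE 0.235, adjusted p = 2.82e-06) and miR-494-3p by 1.57 (SE 0.291, adjusted p = 0.000148). The liver-enriched miR-148a-3p, measured on 2 of 4 control arrays, rose by 1.47 (SE 0.185, adjusted p = 1.67e-06). Other rises fell on miRNAs that were dim in the controls. miR-7668-3p rose by 2.89 and was well above background on 1 of 4 control arrays, miR-212-3p rose by 2.05 with 1 of 4, and miR-3968, miR-6402, miR-23a-5p and miR-8113, well above background on no control array, were at least 1.70-fold, 1.94-fold, 1.30-fold and 1.13-fold higher. miR-883a-5p fell by 3.05 (SE 0.294, adjusted p = 9.65e-08) and miR-882 fell by 2.84 (SE 0.301, adjusted p = 2.7e-07). miR-7080-3p (-3.26), miR-3620-3p (-3.09), miR-300-5p (-2.95), miR-6957-5p (-2.84), miR-7022-3p (-2.57, well above background on 2 of 4 TSN arrays) and miR-7084-5p (-2.43) fell as well. The unscaled signals of miR-7080-3p, miR-3620-3p and miR-7022-3p did not follow array brightness within the control days (slopes of -0.0317, -0.0268 and -0.041). Their unscaled changes averaged only -0.452, -0.374 and -0.22 over the 3 days, and a flat signal divided by brighter arrays falls by construction. miR-883a-5p, miR-882, miR-6957-5p, miR-300-5p and miR-7084-5p did follow brightness (slopes of 0.872, 0.884, 0.914, 0.933 and 0.896). Their unscaled changes still averaged only 0.0257, 0.265, 0.161, 0.25 and 0.571. Their falls thus arise from the division by brightness, whose mean gap between the arms was 2.99. The endothelial and smooth muscle miRNA miR-222-3p fell by 1.23 (adjusted p = 2.17e-06) and the red cell miRNA miR-16-5p fell by 1.08 (adjusted p = 5.3e-05).

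List medians under the alternatives are read, here and below, relative to the median miRNA where a scaling moved it by more than 0.1. Of the let-7 family, 8 of 9 tested members rose at day 3, and its median (0.80) flipped under none of the 9 alternatives, with let-7d-5p at 1.07 and let-7i-5p at 1.02. Camera gave the family an adjusted p of 0.0913, and 8 rose when adjusted over the list alone. In the controls camera called the family higher at days 9 and 21 than at day 3 (adjusted p = 3.32e-05 and 1.26e-05). Both calls were kept in all 9 alternatives and lost with an estimated correlation. The rise at day 3 is thus measured against a control group that was low for this family. In the stellate cell and fibrosis list 4 of 7 rose, miR-29a-3p by 0.91 and miR-29b-3p by 0.67 among them, and the median (0.47) flipped under no alternative (camera adjusted p = 0.562). In the miR-17 superfamily, which holds miR-106b-5p, 6 of 11 rose, 2 fell and 3 did not pass; miR-17-5p was at least 1.58-fold higher, and the median (0.45) flipped under total gene signal (camera adjusted p = 0.562). Of 5 miR-30 members, miR-30d-5p (-0.75) and miR-30a-5p (-0.66) were among 3 that fell and 1 rose, with a median (-0.50) that flipped with no scaling, hybridisation spike-ins and normexp (adjusted p = 0.562; 2 rose and 3 fell when adjusted over the list alone). In the erythroid list 2 of 6 rose and 2 fell, among them miR-486a-5p (-0.63), and the median (-0.25) flipped under 4 alternatives (4 spike-in probes, no scaling, hybridisation spike-ins and normexp; adjusted p = 0.6). miR-133b-3p, at least 1.38-fold higher, and miR-378a-3p (1.29) were the 2 of 4 muscle and heart miRNAs that rose, with a median (0.93) that flipped under none (adjusted p = 0.643). The call of miR-133b-3p was lost in most alternatives. Read without reference to the median miRNA, miR-133b-3p, miR-378a-3p and miR-17-5p lay below 0 under normexp.

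In the remaining lists at day 3, 1 of 7 liver-enriched miRNAs rose (adjusted p = 0.775) and miR-101b-3p (-0.40) did not pass. Of 6 platelet miRNAs 2 rose, miR-26a-5p and miR-21a-5p (0.47, reversed under quantile normalization and the authors' values), and 1 when adjusted over the list alone (adjusted p = 0.608). Of 8 leukocyte miRNAs 2 rose and 2 fell, with miR-142a-5p at 1.08 and miR-150-5p at -1.32 (adjusted p = 0.775). Of 6 vascular miRNAs 2 fell (adjusted p = 0.562), miR-222-3p and miR-126a-5p (-0.69, well above background on no control array and so without a measured size). Of 6 miR-15/16 members 1 rose, miR-322-5p (0.95), and 1 fell, miR-16-5p (adjusted p = 0.775). Of 4 Dlk1-Dio3 miRNAs 1 rose, miR-494-3p, while miR-134-5p (0.23) did not pass (adjusted p = 0.643). Of 8 Sfmbt2 miRNAs 4 rose, miR-669f-3p (0.81) and miR-466i-5p (1.35) among them (adjusted p = 0.562). Among 164 late miRBase entries 39 rose and 34 fell (adjusted p = 0.562), and miR-5103 (0.77), whose control mean of -6.19 lay near the floor with no array well above background, passed without a measured size. Counts adjusted over the list alone, at days 3, 9 and 21 of TSN against control, were the same where not given. With an estimated correlation, camera's adjusted p was 0.868 in each of the 14 lists. Over all 444 miRNAs tested, 129 rose and 81 fell at day 3. Of these 210, 99 (48 higher, 51 lower) were measured on every array of both groups. Among the higher calls 49 had no control array well above background, and only 15 of these had a bound above 1-fold; among the lower calls 7 had none. Relative to the median miRNA where a scaling moved it by more than 0.1, day 3 changes reversed under normexp for miR-16-5p, miR-486a-5p and miR-30a-5p, with no scaling and hybridisation spike-ins for miR-486a-5p, miR-30a-5p, miR-134-5p and miR-5103 (and for miR-30d-5p with no scaling), with 4 spike-in probes for miR-5103, and under total gene signal for miR-17-5p, miR-133b-3p, miR-212-3p, miR-300-5p, miR-322-5p and miR-669f-3p.

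TSN against control at day 9 asked the same after 9 days. The muscle miRNA miR-133b-3p was at least 21.1-fold higher (fitted change 6.17, SE 0.582, adjusted p = 3.22e-08; TSN SD 1.61) and miR-133a-3p at least 6.35-fold higher (4.54, SE 0.534, adjusted p = 5.96e-07), and neither was well above background on any control array. miR-1a-3p, of the same tissue, rose by 2.77 (SE 0.436, adjusted p = 2.15e-05) and was well above background on 1 of 4 control arrays. The red cell miRNAs miR-144-3p and miR-486a-5p rose by 1.60 (SE 0.241, adjusted p = 1.36e-05) and 1.28 (SE 0.216, adjusted p = 4.29e-05), miR-148a-3p rose by 1.59 (adjusted p = 5.25e-07), and miR-15a-5p by 1.32 (SE 0.205, adjusted p = 1.91e-05). miR-6931-5p (2.66), miR-7668-3p (2.56) and miR-3082-5p (2.54) rose too, and miR-3968 was at least 1.06-fold higher. miR-883a-5p fell by 4.10 (SE 0.294, adjusted p = 3.09e-09), miR-882 fell by 3.81 (SE 0.301, adjusted p = 5.28e-09) and miR-222-3p fell by 1.78 (SE 0.157, adjusted p = 1.3e-08). Other falls were those of miR-7080-3p (-3.85), miR-6957-5p (-3.64), miR-3620-3p (-3.62), miR-300-5p (-3.60), miR-7084-5p (-3.26), miR-3099-3p (-3.26) and the leukocyte miRNA miR-142a-3p (-1.54, adjusted p = 0.000131). The limit of a flat unscaled signal given at day 3 holds here for miR-7080-3p and miR-3620-3p. The small unscaled changes given there for miR-883a-5p, miR-882, miR-6957-5p, miR-300-5p and miR-7084-5p apply here too. That of miR-3099-3p averaged 0.697.

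Of the 4 muscle and heart miRNAs 3 rose at day 9, and camera gave the list adjusted p = 0.0262. This call was lost under 8 of the 9 alternatives and kept under normexp (adjusted p from 0.0075 to 0.335), and lost with an estimated correlation (adjusted p = 0.774), while the median (3.65) flipped under none. Adjusted over the list alone all 4 rose, miR-378a-3p (1.05) being the one that did not pass over all miRNAs. miR-206-3p, miR-208a-3p and miR-499-5p were not well above background on any array. In the miR-17 superfamily 8 of 11 rose, among them miR-17-5p (1.73, with 1 of 4 control arrays well above background), and 1 fell (camera adjusted p = 0.0262). This call was lost under 6 of the 9, kept with all probes, 4 spike-in probes and normexp (adjusted p from 2.11e-07 to 0.295), and lost with an estimated correlation (adjusted p = 0.85), while the median (0.75) flipped under none. In the erythroid list 4 of 6 rose and 1 fell, with a median (0.91) that flipped under none (adjusted p = 0.195). Of 7 liver-enriched miRNAs 3 rose, miR-148a-3p, miR-101a-3p (0.94) and miR-192-5p (1.41), with a median (0.94) that flipped under none on the relative reading (adjusted p = 0.195). Read without reference to the median miRNA, miR-148a-3p and miR-101a-3p lay below 0 under normexp, as did miR-1a-3p and miR-17-5p of the lists above. Without replicate 4 of the TSN group miR-192-5p was at 0.633 (limma adjusted p = 0.0617, in a range of 0.00354 to 0.0617 over the arrays left out in turn) and 2 of 7 rose. Of 6 vascular miRNAs 4 fell and 1 rose, with a median (-0.86) that flipped under normexp (adjusted p = 0.328). The vascular miR-126a-5p (-1.27) was well above background on no control array, so its fall has no measured size.

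**Figure D3:**
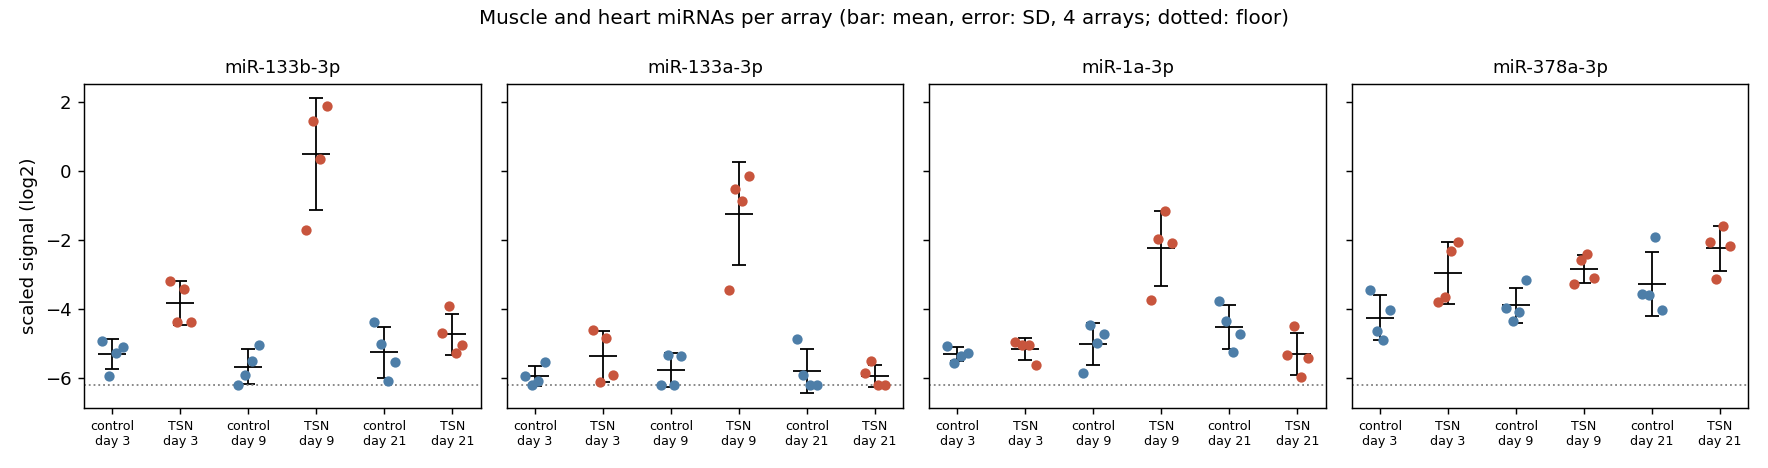
Scaled log2 signal of miR-133b-3p, miR-133a-3p, miR-1a-3p and miR-378a-3p on each of the 4 arrays of the 6 groups, with the mean (bar), SD (error line) and the floor (dotted line, -6.21). The miR-133b-3p mean of the TSN day 9 group is 0.49 against -5.68 in its control group. Read relative to the median miRNA, the median rise of the list flipped under none of the 9 alternatives of scaling, background and authors' values, while its camera call was lost under 8 of them.

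In the remaining lists at day 9, 2 of 7 stellate cell and fibrosis miRNAs rose, miR-29a-3p (0.74) and miR-29c-3p (0.77), and 1 fell, miR-21a-5p (-0.54; camera adjusted p = 0.619). Of 6 platelet miRNAs 3 fell, miR-126a-3p (-0.81) among them (adjusted p = 0.594). Of 8 leukocyte miRNAs 3 fell, miR-142a-3p and miR-150-5p (-1.18) among them (adjusted p = 0.609). Of 9 let-7 members 3 rose and 1 fell, with let-7i-5p at 0.72 and let-7e-5p at -1.29 (camera adjusted p = 0.734). No control array was well above background for let-7e-5p, so its fall has no measured size. Of 5 miR-30 members 1 rose and 2 fell, miR-30d-5p (-0.73) and miR-30e-5p (-0.58; adjusted p = 0.995; 2 rose when adjusted over the list alone). Of 6 miR-15/16 members 2 rose, miR-15a-5p and miR-15b-5p (0.92; adjusted p = 0.328). Of 4 Dlk1-Dio3 miRNAs 1 rose, miR-494-3p (1.49), and 1 fell, miR-370-3p (-0.54; adjusted p = 0.539). Of 8 Sfmbt2 miRNAs 2 rose, miR-466i-5p (2.33) among them, and 3 fell, miR-466h-3p (-1.47, no control array well above background and so without a measured size) among them (adjusted p = 0.935). Of 164 late miRBase entries 41 rose, miR-5103 (1.38, every control array at the floor, so without a measured size) among them, and 70 fell (adjusted p = 0.195). Over the 444 miRNAs, 124 rose and 152 fell at day 9. Of these 276, 114 (38 higher, 76 lower) were measured on every array of both groups. Among the higher calls 42 had no control array well above background, 4 of them with a bound above 1-fold, and among the lower calls 25 had none. Relative to the median miRNA where a scaling moved it by more than 0.1, day 9 changes reversed for miR-21a-5p and miR-370-3p under 5 scalings (all probes, 4 spike-in probes, none, hybridisation spike-ins and normexp), for miR-30e-5p under the first 4 of these, for miR-30d-5p under 3, for miR-126a-3p under 3, for miR-142a-3p and miR-5103 under normexp, and for miR-300-5p and miR-466h-3p under total gene signal.

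TSN against control at day 21 asked what remained after 21 days. miR-494-3p rose by 2.44 (SE 0.291, adjusted p = 1.58e-06). miR-3968, miR-8090, miR-6402 and miR-6934-5p, well above background on no control array, were at least 4.44-fold, 2.88-fold, 3.15-fold and 1.92-fold higher, and miR-7668-3p (2.60), miR-212-3p (2.20) and miR-135a-1-3p (2.15), each measured on 2 of 4 control arrays, rose. miR-22-3p fell by 2.08 (SE 0.188, adjusted p = 3.92e-08), miR-222-3p fell by 1.92 (SE 0.157, adjusted p = 1.47e-08), miR-140-5p fell by 1.86 (SE 0.139, adjusted p = 4.93e-09) and miR-221-3p, clustered with miR-222-3p, fell by 1.49 (adjusted p = 1.64e-06). miR-7080-3p (-2.61), miR-3620-3p (-2.33), miR-7022-3p (-1.77, well above background on 2 of 4 TSN arrays), miR-883a-5p (-1.70) and miR-486a-3p (-1.61, adjusted p = 6.09e-06) fell too. For the first 3 of these, the limit of a flat unscaled signal given at day 3 holds. For miR-883a-5p, the small unscaled change given there applies.

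Of 6 vascular miRNAs 4 fell at day 21 and 2 rose, with a median (-0.63) that flipped under none of the 9 alternatives on the relative reading (camera adjusted p = 0.27). Read without reference to the median miRNA, miR-221-3p and miR-222-3p of this list lay above 0 with no scaling and with hybridisation spike-ins. miR-221-3p did so with the 4 spike-in probes too. Of 6 miR-15/16 members 4 fell, miR-16-5p (-1.33) and miR-195a-5p (-0.64) among them, and the median (-0.53) flipped under normexp (adjusted p = 0.102). Of 8 leukocyte miRNAs 4 fell, miR-223-3p (-1.09) and miR-146a-5p (-0.89) among them, and the median (-0.71) flipped under normexp (adjusted p = 0.126). Of 6 platelet miRNAs 4 fell, miR-223-3p and miR-21a-5p (-0.65) among them, with a median (-0.54) that flipped under normexp (adjusted p = 0.27). Of 6 erythroid miRNAs 2 fell, miR-16-5p and miR-144-5p (-1.07), and the median (-0.41) flipped with no scaling, hybridisation spike-ins and normexp (adjusted p = 0.183). Of 5 miR-30 members 3 fell, miR-30d-5p (-0.56) and miR-30e-5p (-0.49) among them (adjusted p = 0.183). In the miR-17 superfamily 2 of 11 rose, miR-106b-5p and miR-17-5p (1.08), and 3 fell, miR-19a-3p (-1.43) among them (adjusted p = 0.747). Of 7 liver-enriched miRNAs 1 rose, miR-148a-3p (0.69), and 1 fell, miR-101b-3p (-0.77; adjusted p = 0.97). Of the 4 muscle and heart miRNAs 0 passed limma's threshold, miR-378a-3p (1.03) and miR-1a-3p (-0.79) included (camera adjusted p = 0.97).

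In the remaining lists at day 21, 1 of 7 stellate cell and fibrosis miRNAs fell, miR-21a-5p, and miR-29b-3p (-0.35) did not pass (adjusted p = 0.486). Of 9 let-7 members 1 fell, let-7e-5p (-0.53), which was not called when adjusted over the list alone, and let-7d-5p (0.32) did not pass (adjusted p = 0.97). Of 4 Dlk1-Dio3 miRNAs 1 rose, miR-494-3p, and miR-370-3p (0.49) did not pass (adjusted p = 0.278). Of 8 Sfmbt2 miRNAs 3 fell, miR-669f-3p (-0.84) and miR-466f-3p (-0.82) among them, and 2 when adjusted over the list alone (adjusted p = 0.486). Of 164 late miRBase entries 48 rose, miR-5103 (0.77, every control array at the floor) among them, and 24 fell (adjusted p = 0.102). Over the 444 miRNAs, 103 rose and 96 fell at day 21. Of these 199, 84 (27 higher, 57 lower) were measured on every array of both groups. Among the higher calls 29 had no control array well above background, 8 of them with a bound above 1-fold, and among the lower calls 3 had none. On the same relative scale, day 21 changes reversed for miR-16-5p, miR-223-3p, miR-21a-5p and miR-29b-3p under normexp, for miR-7080-3p under total gene signal, for miR-30e-5p with no scaling and hybridisation spike-ins, and for miR-5103 with these and 4 spike-in probes. Camera passed 0, 2 and 0 of the 14 lists at days 3, 9 and 21, and with an estimated correlation 0 at each, while fry, which does not compare a list with other miRNAs, passed 7, 10 and 8.

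Many of the same miRNAs were called at several days. The TSN groups shared 61 higher and 58 lower miRNAs at all 3 days, where independent lists would share 8.36 and 6. Days 3 and 9 shared 86 higher and 74 lower (36 and 27.7 for independent lists), days 3 and 21 shared 74 and 63 (29.9 and 17.5), and days 9 and 21 shared 70 and 75 (28.8 and 32.9), with 7, 4 and 4 called in opposite directions. The changes correlated at 0.813, 0.799 and 0.676 across the 444 miRNAs, which are not independent replicates. No control array was used at more than 1 day, but all days shared the separation of the arms by slide. The 4 TSN arrays did not overlap the 4 control arrays for 180, 229 and 170 miRNAs (40.5%, 51.6% and 38.3%, against 2.86% by chance). With a 2-fold minimum the calls were 57 higher and 50 lower, 53 and 82, and 45 and 47.

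The division into higher and lower miRNAs depended on the scaling. At days 3, 9 and 21 the calls were 129 higher and 81 lower, 124 and 152, and 103 and 96. Dividing by the percentile over all probes gave 188 and 34, 242 and 28, and 92 and 44, scaling to the 4 spike-in probes 366 and 11, 368 and 13, and 359 and 3, and no scaling 387 and 2, 395 and 5, and 416 and 0. The percentile over all probes was only 0.735 to 2.07 intensity units on control arrays and 3.079 to 7.166 on TSN arrays. At most 25.04% of miRNAs were well above background on an array, so this percentile lies near background. The labelling spike-ins gave 298 and 23, 323 and 23, and 232 and 14, and the hybridisation spike-ins 399 and 2, 399 and 6, and 419 and 0. Normexp gave 23 and 351, 30 and 375, and 17 and 345, the authors' values 219 and 68, 258 and 77, and 145 and 70, quantile normalization 133 and 80, 156 of 261 calls higher at day 9, and 93 and 91, and total gene signal 111 and 67, 115 and 91, and 84 and 60. A filter on all 24 arrays gave 41 and 43, 37 and 72, and 24 and 46. Normexp adds its offset of 50 to every signal before the division by brightness. The 75th percentile of the processed signal was 73.55 to 609.2 on control arrays and 736.8 to 1748 on TSN arrays. The offset thus weighs more on the control arrays and by construction lowers dim miRNAs in the TSN groups. Its share of the normexp calls was not tested. Taken without reference to the median, 10 of 15, 13 of 19 and 20 of 22 named lower calls lay above 0 with no scaling, a setting that moves all miRNAs of an array alike, and 13, 8 and 8 of the 25, 21 and 12 named higher calls lay below 0 under normexp. The median change of the 444 miRNAs moved by 0.51, 0.80 and 0.17 with all probes, 1.56, 1.89 and 1.40 with 4 spike-in probes, 2.09, 2.45 and 2.05 with no scaling, 0.89, 1.21 and 0.66 with labelling spike-ins, 2.19, 2.46 and 2.16 with hybridisation spike-ins, -1.61, -1.70 and -1.18 with normexp and 0.19, 0.37 and 0.16 with the authors' values. With total gene signal it moved by 0.20 at day 3 and 0.11 at day 21.

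**Figure D4:**
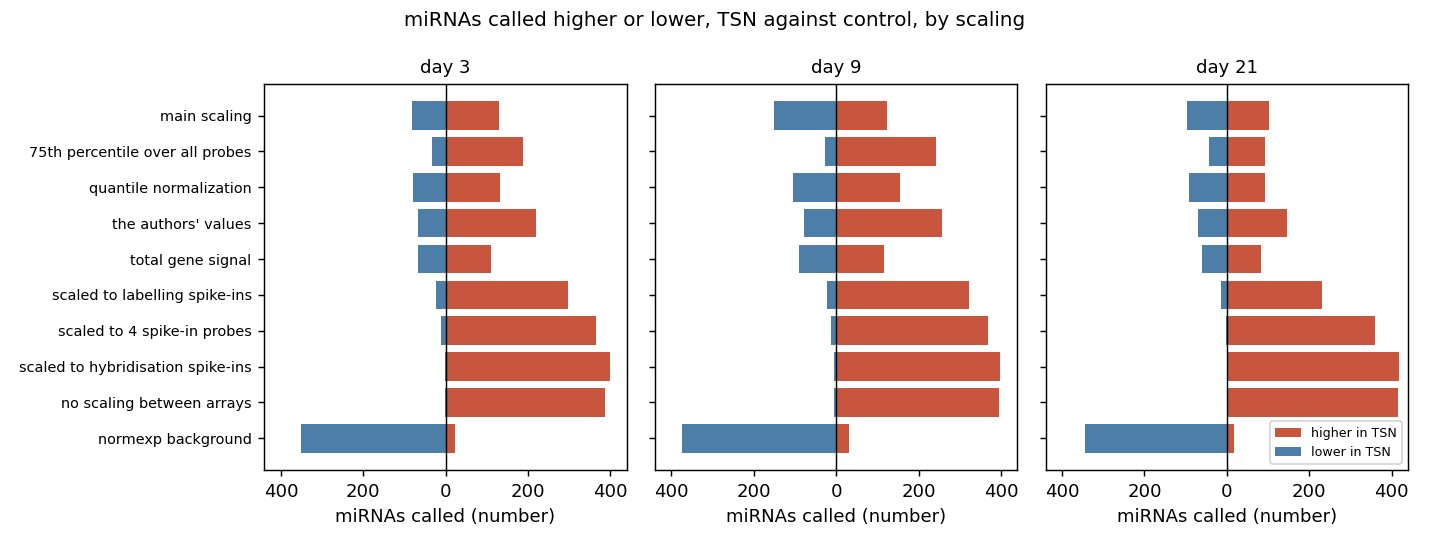
Number of miRNAs called higher and lower (count axis) in TSN against control under each scaling, for days 3, 9 and 21. Higher calls range from 23 to 399 and lower calls from 2 to 351 at day 3, so the share that is lower depends on the scaling. The 23 and 351 are those of normexp, whose offset weighs more on the dimmer control arrays.

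The interaction tests asked whether the TSN effect differed between days, relative to the scaling of each. The effect on miR-106b-5p was larger at day 9 than at day 3 by 1.00 (SE 0.267, adjusted p = 0.0119) and smaller at day 21 than at day 9 by -1.32 (SE 0.267, adjusted p = 0.00128). Day 21 minus day 3 (-0.32, adjusted p = 0.496) did not pass. The first difference was lost under 7 alternatives (quantile normalization among them) and the other with no scaling and with hybridisation spike-ins. From day 3 to day 9 the effect rose for miR-486a-5p (1.92, adjusted p = 0.000289), miR-140-3p (0.85, adjusted p = 0.00046) and miR-5103 (0.61, with its controls at or near the floor) and fell for miR-338-3p (-2.36), miR-466h-3p (-2.10) and miR-7217-5p (-2.04). No control array of these days was well above background for miR-466h-3p, and none of day 3 for miR-338-3p, so their falls have no measured size. miR-7217-5p was not measured on all control arrays. From day 9 to day 21 it fell for miR-133b-3p (-5.64, SE 0.823, adjusted p = 0.000311), miR-674-3p (-1.56) and miR-5103 (-0.61), and rose for miR-883a-5p (2.40), miR-6934-5p (1.74) and miR-6995-5p (1.31). For miR-133b-3p 0 of 4 control arrays were well above background at day 9 and 1 of 4 at day 21, so the size of its fall rests on unmeasured controls. From day 3 to day 21 it rose for miR-8093 (1.22), miR-1957a (1.12) and miR-6915-5p (1.07) and fell for miR-669f-3p (-1.65, adjusted p = 0.00329), miR-142a-5p (-1.23) and miR-130b-3p (-1.16). The effect passed as different for 84 miRNAs between days 3 and 9 (17 higher, 67 lower), 58 between days 3 and 21 (18 higher, 40 lower) and 154 between days 9 and 21 (102 higher, 52 lower). These balances turned with the scaling. Between days 3 and 9 all probes gave 31 higher and 4 lower, labelling spike-ins 31 and 6, 4 spike-in probes 12 and 2, no scaling 11 and 4, hybridisation spike-ins 12 and 8 and the authors' values 26 and 15. Between days 9 and 21 they gave 8 and 127, 7 and 123, 12 and 84, 11 and 31, 10 and 19, and 43 and 98, and quantile normalization 66 and 82. Between days 3 and 21, 4 spike-in probes gave 3 and 1, no scaling 5 and 0, and hybridisation spike-ins 4 and 2. In limma 0 passed there under normexp and without the 2 dimmest control arrays of each day (32 and 96 at unadjusted p under 0.05), and leaving out each array in turn gave 29 to 70. Between days 9 and 21, camera called the miR-17 superfamily (adjusted p = 2.91e-06, and adjusted p = 0.153 with an estimated correlation), the erythroid list (0.000131, and 0.153) and the muscle and heart list (0.000697, and 0.153) lower. Over the 9 alternatives the first of these calls was kept in all, the erythroid one lost with the authors' values (adjusted p from 1.86e-11 to 0.0562) and the muscle one lost with total gene signal (0.000102 to 0.0601). Camera passed 6, 8 and 6 lists in the order of the counts, 1 to 8, 4 to 8 and 5 to 6 over the alternatives, and 0 with an estimated correlation.

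Within the control arm, day 9 against day 3 was measured on 1 slide. miR-338-3p (at least 1.02-fold) and miR-181d-5p (at least 1.01-fold) were higher at day 9, each well above background on 1 of 4 arrays there and none at day 3, and miR-466h-3p (1.38) passed with no array well above background in either group. miR-149-3p (-0.70), miR-877-5p (-0.71) and miR-3960 (-0.58) fell. The counts were 42 higher and 19 lower, 9 and 19 with the authors' values and 2 and 5 with labelling spike-ins. In limma 0 passed with all probes, 4 spike-in probes, no scaling, normexp and hybridisation spike-ins (42, 18, 5, 11 and 6 at unadjusted p under 0.05), and 19 to 68 when each array was left out in turn. In the let-7 family 4 of 9 rose, and 8 when adjusted over the list alone, with a median (0.66) that flipped under none of the 9 alternatives (camera adjusted p = 3.32e-05, kept in all 9, and adjusted p = 0.418 with an estimated correlation). Camera passed 6 lists, 2 to 9 over the alternatives, and 0 with an estimated correlation. At day 21 against day 3, which lie on different slides, let-7g-5p (1.05, adjusted p = 0.000266) and miR-223-3p (1.14, adjusted p = 0.000316) rose, as did miR-338-3p (at least 1.09-fold), and miR-504-3p (-0.81), miR-8110 (-0.72) and miR-1224-5p (-0.58) fell, among 75 higher and 26 lower. In limma 0 passed there with no scaling and with hybridisation spike-ins (79 and 65 at unadjusted p under 0.05), 1 with normexp and 34 with the compared groups alone, and leaving out each array in turn gave 63 to 101. At day 21 against day 9, miR-6238 (1.09, adjusted p = 0.021) rose and miR-504-3p (-0.65, adjusted p = 0.0329) fell, the 2 calls made. All probes gave 102 calls and the authors' values 30, all higher, and leaving out each array in turn 0 to 28. Read without reference to the median, miR-504-3p lay above 0 with all probes, 4 spike-in probes, no scaling and the authors' values. miR-106b-5p passed in none of these, at 0.11, 0.34 and 0.23 in the same order (adjusted p = 0.814, 0.215 and 0.586).

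Within the TSN arm, day 21 against day 9 was also measured on 1 slide. miR-133b-3p fell by 5.23 (SE 0.582, adjusted p = 5.12e-06), miR-133a-3p fell by 4.71 (SE 0.534, adjusted p = 5.12e-06), miR-106b-5p fell by 1.09 (SE 0.189, adjusted p = 0.000215) and miR-5103 fell by 0.61 (adjusted p = 9.87e-08). miR-3963 (2.12), miR-6934-5p (1.74) and miR-6995-5p (1.22) rose. The fall of miR-106b-5p was lost with no scaling (adjusted p = 0.0903) and with hybridisation spike-ins (adjusted p = 0.08), in a range of 5.82e-07 to 0.0903, as was the rise of miR-6995-5p. The fall of miR-133a-3p was lost with total gene signal, miR-6934-5p and miR-5103 reversed there, and under normexp miR-6934-5p was lost and miR-5103 reversed. The counts were 136 higher and 57 lower, a balance that turned to 34 and 74 with all probes, 34 and 90 with labelling spike-ins, 38 and 58 with 4 spike-in probes and 63 and 65 with the authors' values. In the miR-17 superfamily 6 of 11 fell, and 8 when adjusted over the list alone, with a median (-0.66) that flipped under none of the 9 alternatives (camera adjusted p = 1.64e-05, kept in all 9, and adjusted p = 0.188 with an estimated correlation). In the erythroid list 4 of 6 fell with a median (-0.95) that flipped under none (camera adjusted p = 0.000424, lost with quantile normalization, and adjusted p = 0.188 with an estimated correlation). In the muscle and heart list 3 of 4 fell with a median (-3.89) that flipped under none (0.00079, lost with total gene signal, and 0.188). Late miRBase entries rose, 70 of 164, while 4 fell, with a median (0.36) that flipped under none (8.61e-06, kept in all 9, and 0.334).

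Between TSN days 9 and 3, which lie on different slides of 1 scan date, miR-106b-5p rose by 1.11 (SE 0.189, adjusted p = 0.000214), miR-133b-3p by 4.34 (adjusted p = 2.81e-05), miR-133a-3p by 4.13 (adjusted p = 2.24e-05) and miR-5103 by 0.60 (adjusted p = 1.41e-07), and miR-714 (-1.55), miR-5130 (-1.28) and miR-6995-5p (-1.25) fell, among 44 higher and 111 lower. This balance turned to 59 and 27 with all probes, 78 and 29 with labelling spike-ins, 56 and 26 with 4 spike-in probes, 49 and 20 with no scaling, 44 and 22 with hybridisation spike-ins and 59 and 54 with the authors' values. The rise of miR-106b-5p was lost with no scaling (adjusted p = 0.0934) and with hybridisation spike-ins (adjusted p = 0.0977), in a range of 3.3e-05 to 0.0977, as was the fall of miR-6995-5p. The rise of miR-133a-3p was lost with total gene signal, as were the falls of miR-714 (lost under normexp too) and miR-5130. The rise of miR-5103 reversed under both and was lost with the authors' values. Camera passed 7 lists, 5 to 7 over the alternatives, and 0 with an estimated correlation. At day 21 against day 3, miR-30d-5p rose by 0.85 (adjusted p = 4.9e-05), and miR-8093 (1.53) and miR-1957a (1.31) rose, while miR-208a-5p (-1.75), miR-294-5p (-1.11) and miR-542-5p (-1.05) fell, among 20 higher and 11 lower (33 and 49 with array weights, 0 and 1 with normexp, and 13 to 38 calls when each array was left out in turn). The call of miR-30d-5p was lost under 6 scalings, and miR-106b-5p (0.03, adjusted p = 1) did not pass. Of 5 miR-30 members 3 rose there (camera adjusted p = 0.00048, lost under 5 of the 9 alternatives in a range of 0.00296 to 0.494, and adjusted p = 0.162 with an estimated correlation).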

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

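Of the tests in this part, the counts of other splits were planned and the 10 tests of technical and biological explanations were chosen only after the results were seen. In 17 of the 274 groups of 4 arrays of named miRNAs (6.2%, where chance gives about 1 in 20), 1 array stood far from the other 3, and in none of 18 groups of array measures. The share of the group's range taken up by the gap was 0.904 for miR-486a-5p in control day 3 (replicate 4), 0.88 for miR-26a-5p (replicate 1), 0.893 for miR-222-3p (replicate 2) and 0.978 for miR-29b-3p (replicate 2) in the same group. It was 0.918 for miR-3082-5p and 0.96 for miR-466i-5p in control day 9 (replicate 1), 0.873 for miR-877-5p and 0.856 for miR-3960 (replicate 2) and 0.891 for miR-140-3p (replicate 3) there, and 0.848 for miR-195a-5p in control day 21 (replicate 4). In the TSN groups it was 0.882 for miR-150-5p at day 3 (replicate 3), 0.834 for miR-150-5p at day 9 (replicate 4), and at day 21 0.833 for miR-8090, 0.899 for miR-21a-5p, 0.869 for miR-5103 and 0.833 for miR-130b-3p (replicate 2) and 0.952 for miR-17-5p (replicate 3).

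The effect of TSN differed between days by the interaction test of limma. From day 3 to day 9 it differed for 84 miRNAs, among them miR-106b-5p (1.00, lost under 7 alternatives), miR-486a-5p (1.92), miR-140-3p (0.85), miR-5103 (0.61, with its controls at or near the floor), miR-338-3p (-2.36), miR-466h-3p (-2.10) and miR-7217-5p (-2.04). The values of miR-338-3p and miR-466h-3p have no measured size, since no control array of day 3 was well above background for them. From day 3 to day 21 it differed for 58, among them miR-8093 (1.22), miR-1957a (1.12), miR-6915-5p (1.07), miR-669f-3p (-1.65), miR-142a-5p (-1.23) and miR-130b-3p (-1.16), but in limma for 0 under normexp and 0 without the 2 dimmest control arrays of each day (32 and 96 at unadjusted p under 0.05). From day 9 to day 21 it differed for 154, among them miR-883a-5p (2.40), miR-6934-5p (1.74), miR-6995-5p (1.31), miR-106b-5p (-1.32, lost under 2), miR-5103 (-0.61), miR-133b-3p (-5.64, with no day 9 control array well above background) and miR-674-3p (-1.56). Of 100 splits drawn for each, 4, 1 and 1, the real one included, called as many. Each split shuffled the days within each arm. It thus asks whether the days differ in either arm, not whether the effect of TSN differs between them. On that question a chance split is excluded for days 3 and 21 and for days 9 and 21. For days 3 and 9 the share lay under the limit set beforehand, but the real 84 lay within the range of the other splits. The highest other splits called 141, 27 and 78. For days 3 and 9 another 3 splits called as many as the real one or more, and what they share was not tested.

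For TSN against control at days 3, 9 and 21, 1, 1 and 1 of 35 splits called as many as the real 210, 276 and 199, which excludes a chance split, with 15, 104 and 85 in the highest other. For control day 9 against day 3 and day 21 against day 3, 1 and 1 of 35 called as many as the real 61 and 101 (highest other 5 and 33), which excludes it too. For control day 21 against day 9, 5 of 35 called as many as the real 2, with 26 in the highest other, so that a chance split was not excluded. For TSN day 9 against day 3, day 21 against day 3 and day 21 against day 9, 1, 1 and 1 of 35 called as many as the real 155, 31 and 193 (highest other 137, 7 and 70), which excludes it. Of the 35 splits, 8 part all replicate pairs, the real one among them. The highest other of these called 15, 0 and 0 in TSN against control at days 3, 9 and 21, against 5, 104 and 85 among splits that keep pairs together, and 137 in TSN day 9 against day 3.

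Several control probes that no comparison uses were brighter on TSN than on control arrays. hur_5 was not, with a median near 0 in both arms (0.3319 on control and -0.552 on TSN arrays). The smallest and largest fold over the 3 days were 167 and 218 for hur_1, 12 and 25.5 for hur_2, 10.6 and 27.6 for hur_4, 19.3 and 24.4 for hur_6 and 7.49 and 11 for mr_1. What these probes bind is not given in the files.

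The TSN arrays were brighter than the control arrays. Hybridisation or scanning as the cause is excluded, since the hybridisation spike-ins differed between arms by at most 1.1-fold. Brightness followed the labelling spike-ins among the 12 control arrays (r = 0.935, slope 1.37, SE 0.164, permutation p = 1e-05, the smallest they can give, adjusted p = 2e-05 over both arms) but not detectably among the 12 TSN arrays (r = 0.225, slope 0.423, SE 0.58, permutation p = 0.49, adjusted p = 0.49). The TSN arrays lay 1.67 residual SDs above the line of the controls on average, all inside its interval, so that better labelling as the whole cause cannot be told apart from other causes, and the line it is judged by rests on the control arm alone. The labelling spike-ins spanned 209.2 to 765 on control arrays and 1104 to 1670 on TSN arrays. The line and its interval were thus extrapolated to every TSN array. Brightness over the labelling spike-ins was at least 1.77-fold higher in the TSN groups (2.14, 3.35 and 1.77 at days 3, 9 and 21), and more miRNA in the TSN samples, the biological explanation, cannot be told apart from a slide effect because no slide held both arms. The same separation leaves a slide difference open for every comparison of the arms.

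Many miRNAs were lower in the TSN groups after scaling. For most of the 86 of 175 lower calls measured on all control arrays, the slopes argue against a constant background as the cause. Their unscaled signal followed array brightness within the control days with a median slope of 0.998 (quartiles 0.906 and 1.07). Brightness is itself taken from probes well above background on all arrays, so the slopes are not independent of it. A constant background stays open for the other, dim lower calls, whose slope of 0.947 is taken near the floor. For the 12 lower calls with a slope under 0.25 (miR-3620-3p, miR-7022-3p and miR-7080-3p measured on all control arrays, 9 not), the median unscaled change was -0.413 against 2.38 for the other 163, which a constant background predicts. Division by array brightness cannot be told apart from a lower share of these miRNAs in the TSN samples, since 93.7% of the lower calls had a higher unscaled signal in the TSN groups but 98.9% had a decrease smaller than the gap in brightness, which fixes that outcome. The lower share, the biological explanation, was not tested.

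miR-106b-5p was higher in the TSN groups. The erythroid list as a set argues against red cell lysis as the whole cause. Within arrays miR-106b-5p rose by at least 0.949 (SE 0.116) more than the median of the 6 erythroid members at each day under each of the 9 alternatives of scaling, background and authors' values. Scalings by a factor per array cannot change this difference. Only quantile normalization, normexp, total gene signal and the authors' values could. Of single members at days 3, 9 and 21, all 18 differences exceeded 2 standard errors as scaled for the report, 15 under the authors' values and 16 under normexp. Against miR-451a the authors' values gave 0.255, 0.289 and -0.553, so that lysis stays open by that member. The lysis index, miR-451a minus miR-23a-3p on each array, differed by -0.94, 0.3832 and -0.07 (exact permutation p = 0.0571, 0.171 and 0.714, adjusted p = 0.0734, 0.192 and 0.714), so that a part of red cell lysis at day 9 cannot be told apart from an effect of TSN. At day 3 miR-23a-3p was at 1.278 to 1.666 in controls and 2.143 to 2.786 in TSN. miR-451a overlapped there (4.689 to 5.59 and 4.587 to 5.36). The index thus moved with its reference and is no clean measure of red cell content. The choice of scaling is excluded, since the smallest change over days and scalings was 0.859, and an effect of TSN and a difference between slides stay open.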

How the results depend on the processing

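The labelling spike-in scaling, the hybridisation spike-in scaling and the fit without the 2 dimmest control arrays of each day were chosen after the data were seen. The rise of miR-106b-5p kept its direction and its side of the threshold at days 3, 9 and 21 in all alternatives run, and the smallest change over days and scalings, on either reading below, was 0.859. miR-133b-3p and miR-133a-3p at day 9, miR-883a-5p and miR-882 at days 3 and 9, miR-148a-3p at days 3 and 9, miR-494-3p at days 3, 9 and 21, miR-144-3p and miR-486a-5p at day 9, and miR-22-3p, miR-222-3p and miR-140-5p at day 21 also did, in all alternatives that gave them a value, when read relative to the median miRNA where a scaling moved it by more than 0.1. Read without that reference, miR-22-3p, miR-222-3p and miR-140-5p at day 21 and miR-882 at day 3 lay above 0 with no scaling and with hybridisation spike-ins, and miR-148a-3p at days 3 and 9 lay below 0 under normexp. Over the 180 values named or tested, the alternatives gave 3316 values, of which 2781 kept direction and side, 453 lost the threshold, 15 gained it and 67 reversed. Leaving out 1 array gave 1608, with 1550 kept, 51 lost, 7 gained and 0 reversed.

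The day differences of miR-106b-5p were less stable. The larger effect at day 9 than at day 3 (1.00) was lost under quantile normalization (0.46, adjusted p = 0.285), the authors' values (0.60, 0.0983), labelling spike-ins (1.18, 0.0793), 4 spike-in probes (1.21, 0.178), no scaling (1.23, 0.371), hybridisation spike-ins (1.23, 0.382) and no filter (1.00, 0.0591). Over its alternatives the adjusted p ran from 0.00219 to 0.382. With no scaling and with hybridisation spike-ins, the smaller effect at day 21 than at day 9 (-1.84, adjusted p = 0.0617, and -1.76, 0.0836), TSN day 9 against day 3 (1.24, 0.0934, and 1.24, 0.0977) and TSN day 21 against day 9 (-1.21, 0.0903, and -1.25, 0.08) were lost too. The adjusted p of these ran from 0.000155 to 0.0836, 3.3e-05 to 0.0977 and 5.82e-07 to 0.0903 over the alternatives. The cause was not tested here or in what follows.

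Counts of calls are given in 1 order: TSN against control at days 3, 9 and 21, the effect differences of days 9 and 3, 21 and 3, and 21 and 9, control days 9 and 3, 21 and 3, and 21 and 9, and TSN days in the same pairs. They were 210, 276, 199, 84, 58, 154, 61, 101, 2, 155, 31 and 193. The percentile over all probes gave 222, 270, 136, 35, 39, 135, 0, 82, 102, 86, 16 and 108 (where 0 passed in limma, 42 at unadjusted p under 0.05). Quantile normalization gave 213, 261, 184, 67, 71, 148, 50, 109, 7, 144, 36 and 179. The 4 spike-in probes gave 377, 381, 362, 14, 4, 96, 0, 18, 0, 82, 14 and 96 (18 and 99 at unadjusted p under 0.05 where 0 passed). No scaling gave 389, 400, 416, 15, 5, 42, 0, 0, 0, 69, 17 and 70 (5, 79 and 99 where 0 passed). Labelling spike-ins gave 321, 346, 246, 37, 28, 130, 7, 66, 18, 107, 11 and 124. Hybridisation spike-ins gave 401, 405, 419, 20, 6, 29, 0, 0, 0, 66, 15 and 76 (6, 65 and 52 where 0 passed). Normexp gave 374, 405, 362, 20, 0, 41, 0, 1, 0, 55, 1 and 67 (32, 11 and 19 where 0 passed). Total gene signal gave 178, 206, 144, 20, 17, 71, 2, 45, 0, 68, 10 and 100 (60 where 0 passed), and the authors' values 287, 335, 215, 41, 32, 141, 28, 103, 30, 113, 17 and 128.

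Apart from scaling, no filter gave 196, 280, 140, 44, 13, 89, 11, 52, 0, 107, 13 and 143 (147 at unadjusted p under 0.05 in limma where 0 passed). The filter on all 24 arrays, which tests 152 miRNAs, gave 84, 109, 70, 46, 41, 80, 27, 57, 0, 83, 11 and 100 (24 where 0 passed). The 2-fold minimum, which takes calls away by construction, gave 107, 135, 92, 53, 33, 85, 5, 16, 1, 38, 10 and 63. Array weights gave 134, 97 and 225 for the effect differences, 5 for control day 21 against day 9, and 82 for TSN day 21 against day 3. The mean of all probes gave 35 for the effect difference of days 21 and 3, and 6 for control day 21 against day 9. The filter on the compared groups gave 36 for control day 9 against day 3 and 1 for day 21 against day 9, and the trend with robust estimation gave 1 for the latter. The compared groups alone gave 34 for control day 21 against day 3, 0 for day 21 against day 9 (40 at unadjusted p under 0.05) and 17 for TSN day 21 against day 3. Without the 2 dimmest control arrays of each day, the effect difference of days 21 and 3 gave 0 (96 at unadjusted p under 0.05), and the control day comparisons 13, 31 and 13. A halved floor moved no count by more than 1.5 times. The replicate block gave 208, 269, 190, 77, 40, 151, 43, 94, 3, 160, 25 and 191, and changed no call of the named values other than that of miR-133b-3p at day 3. In the model of arm and day, 268 miRNAs were called, and 112 (62 higher, 50 lower) with the slide as a random block (within-slide correlation 0.496). Each slide held arrays of 1 arm only, so the block cannot part arm from slide, and the 112 stay open to a slide difference.

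Leaving out 1 array gave 195 to 211, 256 to 268 and 165 to 195 calls in TSN against control at days 3, 9 and 21, and 62 to 117 and 121 to 183 in the effect differences of days 9 and 3 and of days 21 and 9. For days 21 and 3 it gave 29 to 70, with 33 and 32 without control day 3 replicates 1 and 4, 38 and 31 without control day 21 replicates 2 and 4, and 29 without TSN day 21 replicate 3. Control day 9 against day 3 gave 19 to 68, with 24, 24 and 20 without day 3 replicates 1, 3 and 4, and 19 and 26 without day 9 replicates 2 and 4. Control day 21 against day 3 gave 63 to 101, with 63 without day 21 replicate 4. Control day 21 against day 9 gave 0 to 28. These were 0, 1, 23 and 0 without day 9 replicates 1 to 4, and 28, 0, 0 and 5 without day 21 replicates 1 to 4, where the fits with 0 calls in limma had 55, 72, 51 and 75 at unadjusted p under 0.05. TSN day 9 against day 3 gave 123 to 182, and day 21 against day 9 gave 163 to 216. TSN day 21 against day 3 gave 13 to 38, with 16 without day 3 replicate 1 and 13, 14 and 19 without day 21 replicates 1, 3 and 4.

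Reversed values are given relative to the median miRNA where a setting moved the median change by more than 0.1. The offset of 50 in normexp, which weighs more on the dimmer control arrays, enters its values, and its share was not tested. Under normexp at day 3 miR-16-5p (0.78) and miR-486a-5p (1.26) turned into higher calls, and miR-30a-5p (0.016) turned without a call. At day 9 miR-21a-5p (1.61) turned into a higher call, and miR-126a-3p (0.25), miR-142a-3p (0.36), miR-370-3p (0.079) and miR-5103 (-0.019) turned without one. At day 21 miR-21a-5p (0.83) and miR-29b-3p (0.72) turned into higher calls, and miR-16-5p (0.11) and miR-223-3p (0.31) turned without one. The effect of days 9 and 3 turned for miR-5103 (-0.15), that of days 21 and 9 for miR-5103 (0.24) and miR-674-3p (0.15), and TSN days 9 and 3 (-0.15) and 21 and 9 (0.17) for miR-5103, without calls. Under total gene signal, day 3 values of miR-212-3p (-0.72), miR-300-5p (0.63), miR-133b-3p (-0.076), miR-17-5p (-1.76) and miR-322-5p (-0.26) turned without calls and miR-669f-3p (-4.11) with one. At day 9 miR-300-5p (1.32, called) and miR-466h-3p (0.0087) turned, and at day 21 miR-7080-3p (0.30). In the effect differences miR-5103 (-8.40, called) turned for days 9 and 3, miR-669f-3p (2.30) for days 21 and 3, and miR-6934-5p (-4.53) and miR-5103 (4.18) for days 21 and 9, as did TSN days 9 and 3 for miR-5103 (-8.12, called) and TSN days 21 and 9 for miR-6934-5p (-4.84, called) and miR-5103 (3.87).

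With no scaling, the day 3 values of miR-486a-5p (0.13), miR-30d-5p (0.0035) and miR-30a-5p (0.097) turned without calls and those of miR-134-5p (-0.58) and miR-5103 (-0.64) with them. At day 9 miR-126a-3p (0.30), miR-21a-5p (0.57), miR-30d-5p (0.36), miR-30e-5p (0.51) and miR-370-3p (0.57) turned without calls, as did miR-30e-5p (0.0082) and miR-5103 (-0.31) at day 21. Hybridisation spike-ins turned miR-486a-5p (0.10), miR-30a-5p (0.07022), miR-134-5p (-0.56, called) and miR-5103 (-0.62, called) at day 3, miR-126a-3p (0.30), miR-21a-5p (0.57), miR-30d-5p (0.38), miR-30e-5p (0.52) and miR-370-3p (0.57) at day 9, and miR-30e-5p (0.0078) and miR-5103 (-0.39) at day 21. The 4 spike-in probes turned miR-5103 (-0.28) at day 3, miR-21a-5p (0.23), miR-30d-5p (0.039), miR-30e-5p (0.19) and miR-370-3p (0.23) at day 9, and miR-5103 (-0.011) at day 21. The percentile over all probes turned miR-21a-5p (0.049), miR-30e-5p (0.0074) and miR-370-3p (0.053) at day 9. Quantile normalization (-0.18) and the authors' values (-0.24) turned miR-21a-5p at day 3. In none of the settings of this paragraph other than those marked did a turned value pass the threshold.

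Of the 14 lists, 0, 2 and 0 passed in camera at days 3, 9 and 21, 6 in control day 9 against day 3 and 6 in TSN day 21 against day 9. With an estimated correlation 0 passed in each of these comparisons. With fry, 7, 10 and 8 passed at days 3, 9 and 21. At day 9, 0 passed with quantile normalization, no scaling, labelling spike-ins, hybridisation spike-ins, total gene signal and the authors' values, and 4 with normexp. At day 3, 5 passed with normexp and 1 with total gene signal, and in control day 9 against day 3, 2 passed with the percentile over all probes, no scaling and hybridisation spike-ins. Under normexp the erythroid list turned to higher at day 3 (adjusted p = 0.0223, in a range over the alternatives of 0.0223 to 0.986).

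Signal over background limits what can be said of dim miRNAs. In TSN against control at days 3, 9 and 21, 183, 162 and 179 of the 444 tested miRNAs were measured on every array of both groups, and the TSN arrays measured 379 to 471 miRNAs where the control arrays measured 184 to 351. A miRNA not well above background in the controls has only a bound, and a call between it and a TSN group at the floor has no measured size.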

Other observations

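The within-array differences and the liver miRNA values of this part were chosen only after their values were seen. The cluster that holds miR-106b-5p did not move as a unit. A factor per array leaves the difference between miR-106b-5p and miR-93-5p within an array as it is. It was 1.43 (SD 0.126), 1.43 (SD 0.105) and 1.39 (SD 0.121) in the TSN groups of days 3, 9 and 21 and 0.00373 (SD 0.0457), 0.14 (SD 0.0545) and 0.149 (SD 0.0778) in the controls (n = 4 per group, exact permutation p = 0.0286, adjusted p = 0.0409 over 10 tests at each day, higher in 4 of 4 TSN arrays). Against miR-25-3p the arms differed by 1.32, 0.963 and 1.41 (exact permutation p = 0.0286, adjusted p = 0.0409 at each day). Over all 9 alternatives of scaling, background and authors' values, the step between arms ran from 1.33 to 1.54, 0.924 to 1.33 and 1.20 to 1.24 against miR-93-5p and from 0.97 to 1.43, 0.74 to 0.982 and 1.23 to 1.46 against miR-25-3p. Within slides, control day 9 against day 3 differed by 0.136 against miR-93-5p (exact p = 0.0286, adjusted p = 0.0409) and TSN day 21 against day 9 by -0.0412 (exact p = 0.686, adjusted p = 0.686), and against miR-25-3p these were 0.322 (exact p = 0.0571, adjusted p = 0.0714) and 0.327 (exact p = 0.0857, adjusted p = 0.0952). The step between arms was thus present at each day and follows the slides as it follows the arms, and it shows unequal change of the 2 miRNAs only.

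The liver miRNAs miR-122-5p and miR-192-5p were high on 1 TSN array of day 9. miR-122-5p, the main hepatocyte miRNA, was at 0.97 in replicate 4 and at -3.87, -2.34 and -3.82 in the other 3, with the controls of that day at -4.98, -4.01, -4.30 and -2.78. miR-192-5p was at 1.40 in replicate 4 and at -1.66, -1.26 and -2.20 in the others, with controls at -2.49, -2.43, -2.34 and -2.11. In limma miR-192-5p passed (1.41, SE 0.503, adjusted p = 0.0204) and miR-122-5p, well above background on 2 of 4 control arrays, did not (1.75, SE 0.806, adjusted p = 0.0653). Without replicate 4 neither passed, with miR-192-5p at 0.633 (adjusted p = 0.0617) and miR-122-5p at 0.677 (adjusted p = 0.352). The adjusted p ran from 0.00354 to 0.0617 and from 0.0248 to 0.352 when each array of the 2 groups was left out in turn, and miR-122-5p passed without control replicate 4, TSN replicate 1 or TSN replicate 3. Without TSN replicate 4 other members of the liver-enriched list moved less. miR-148a-3p went from 1.59 to 1.51, miR-101a-3p from 0.941 to 0.872, miR-365-3p from 0.393 to 0.436, miR-101b-3p from -0.435 to -0.494 and miR-193a-3p from 0.239 to -0.148.

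Lists with too few tested members for a list test gave single values. Of the brain list miR-128-3p rose at day 3 (0.96, adjusted p = 0.000682), and in the epithelial list miR-203-3p rose at day 9 (0.79, adjusted p = 0.0036, well above background on no control array and so without a bound above 1-fold) and miR-215-5p fell at day 21 (-0.68, adjusted p = 0.0112). miR-34a-5p passed at day 9 (-0.53, adjusted p = 0.0166), with a TSN mean at the floor and no control array well above background, so its change has no measured size. No pancreas miRNA was tested.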
